A study of Homo sapiens with 12 samples.

How the data were processed

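RNA from H9 human embryonic stem cells under differentiation was taken at days 10, 15, 20 and 25, with 3 libraries per day, all given the same batch in the labels. Per the labels, libraries were made from total RNA by ligation-mediated sequencing (LM-Seq) and sequenced as single reads on an Illumina NovaSeq instrument. The authors deposited a table of raw read counts per gene and library, not normalised, whose columns are named after sorted alignment files, per the file headers. The genome build was GRCh38, per the submitters' processing notes. The aligner, the counter and the annotation are not given in the sources used here, and neither is whether counting used strand, so overlapping and antisense genes cannot be told apart. In each of the 12 libraries more genes had a count of 2 than of 1, so a count need not be an independent fragment.

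The table held 36601 Ensembl gene IDs. A table of gene names gave a symbol for 25321, and the 11280 without one held 0.44% of counts, kept their IDs and stayed in the test. Of 19 symbols shared by several IDs, the ID with the most counts kept the symbol. Coordinates are from GENCODE release 29 on GRCh38. Groups were taken from the days in the labels and no library was left out.

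Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 20183, and libraries were scaled by TMM, with factors from 0.753 to 1.172. All 12 libraries entered a single quasi-likelihood fit (glmQLFit, robust) without covariates, with a common biological coefficient of variation of 6%. Days 15 and 10, 20 and 15, 25 and 20, and 25 and 10 were compared by glmQLFTest, and a joint F test covered the 4 days. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Stage genes passed that threshold with a log2 fold change of at least 1 over each of the other 3 days. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 31 lists with at least 3 tested members, and again with an estimated correlation. Principal components used log2 CPM with a prior count of 2. Shares of counts were compared among days by an exact permutation test of the F statistic over all 15400 partitions of the libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

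The comparisons, the tests, the 32 gene lists, the rule for naming genes and the alternatives were set before the data were examined. Per comparison, the rule took the 6 genes with the largest rise and the 6 with the largest fall among called genes with at least 10 CPM on the higher day, no overlap between the libraries of the days, and a symbol that is not a clone, pseudogene or antisense name. It also took up to 3 members with the largest change, at 1 CPM or more, from each list called by camera or with at least 3 called members. A fixed panel of progenitor, T-cell, cytotoxic and other lineage genes was named whatever its values, and 5 stage genes per day completed it. LCK, CD3D, CD3G and other list members were named from the lists. Some of the genes that the rule took are not reported here.

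The floor was 3 counts, which is 0.0723 to 0.145 CPM in a single library after TMM and, summed over the libraries of a day, 0.03 CPM at days 10 and 20, 0.043 at day 15 and 0.029 at day 25. A fold against a day with 0 counts was computed against the floor of that day and is given as a lower bound. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

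The tests were tested on simulated data drawn from the day 10 means and the sizes of all libraries, with known changes at day 15 in a seeded set of genes. Of 17548 genes fitted, changes of 1.5-fold, 2-fold and 4-fold were recovered in 77.6%, 73.1% and 93.9% of cases, each with the right direction, and 4.7% of 171 calls were false. The changed genes, 67, 67 and 66 for these folds, were few, with rises and falls set in balance. In the data most tested genes differed between days 15 and 10, so these rates need not carry over.

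The alternatives were DESeq2 size factors, library-size scaling, scaling and testing without mitochondrially encoded, ribosomal protein and haemoglobin genes, no filter, a stricter filter (at least 1 CPM and 10 counts in 3 libraries), DESeq2 1.42.0, limma-voom, a replicate block, fits to the libraries of the compared days alone, an adjusted p under 0.01, a minimum change of 2-fold, libraries thinned to equal depth and leaving out each library in turn. The sequence reads themselves were not used here.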

Results

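Bulk RNA sequencing measured gene expression in 12 libraries from H9 cells, an established human embryonic stem cell line, carried through a differentiation protocol directed at γδ T cells. The labels place 3 libraries at day 10 as haematopoietic progenitors, 3 at day 15 and 3 at day 20 as T progenitors, and 3 at day 25 as mature γδ T cells. The medium from day 10 held SCF, IL-7, Flt3L and the Notch ligand DLL4, per the labels. The deposited table gave between 27026196 and 39811230 counts per library, with between 22453 and 24771 genes counted at least once. Levels are mean CPM, counts relative to library size scaled by edgeR's TMM factors, ± SD (n = 3 libraries per day), and folds and log2 fold changes come from edgeR's quasi-likelihood fit with Benjamini-Hochberg adjusted p. The labels do not say whether the 3 replicates of a day were separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

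The 4 days formed 4 separate groups. The first principal component held 57.2% of the variance and set days 10 and 15 apart from days 20 and 25, and the second held 28.7% and parted day 10 from day 15. The third component held 5.9% and parted day 20 from day 25. Of 20183 genes tested, 18256 (90.5%) differed among the 4 days at an adjusted p under 0.05, with replicate libraries of a day lying close together on each component.

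**Figure D1:**
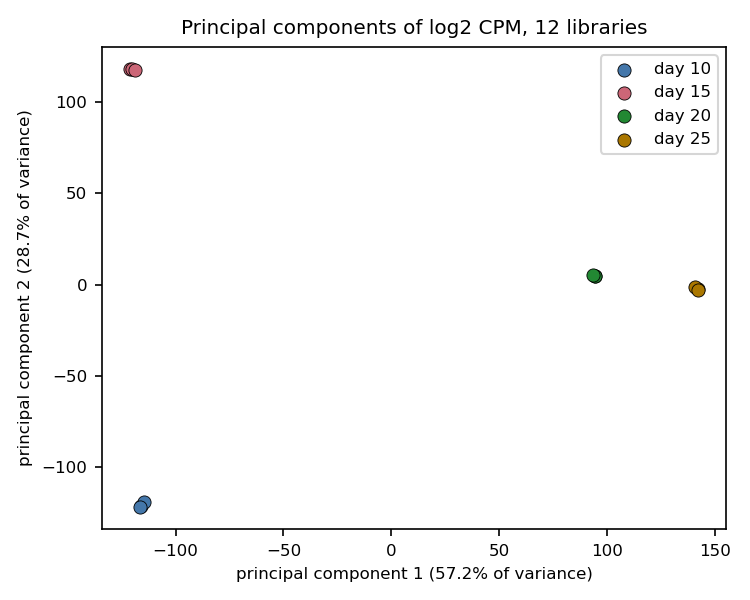
Each point is a library on the first and second principal components of log2 CPM, coloured by day, with 3 libraries per day. Day 10 libraries lie near -115.9 and -121.1, day 15 libraries near -120 and 117.7, and day 20 and day 25 libraries at positive values of component 1.

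Between day 10, when the labels call the cells haematopoietic progenitors, and day 15, when they call them T progenitors, genes of platelet-forming, granulocytic and eosinophilic cells rose. The megakaryocyte genes TUBB1 (388 ± 2.82 to 4721 ± 41.3 CPM), PPBP (594 ± 16.7 to 6766 ± 77.3 CPM) and F13A1 (22.1-fold) rose, as did all 16 tested members of that list. The eosinophil peroxidase gene EPX went from 1.12 ± 0.141 to 3394 ± 93.6 CPM, and the granule genes CLC (301-fold) and CPA3 (337-fold) rose with it. Among myeloid genes, ELANE rose 403-fold, MPO 9.25-fold to 3532 ± 76.7 CPM, and S100A12 at least 518-fold from 0 counts. The neutrophil granule genes OLFM4 (5370-fold) and CEACAM8 (at least 535-fold) were among the largest increases, with DEFA3 at least 10800-fold and its near-identical copy DEFA1 at least 565-fold, which may share reads and are uncertain.

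Cell-cycle genes fell over the same interval, as did some progenitor genes. The stem and progenitor list was not called by camera (adjusted p = 0.89), with 9 members higher and 9 lower. TAL1 rose 3.22-fold and MEIS1 4.06-fold. CD34, the surface marker of early blood progenitors, fell from 20.6 ± 1.79 to 5.47 ± 0.853 CPM (adjusted p = 1.8e-14), and KIT fell 2.57-fold. MKI67 fell from 835 ± 52.7 to 160 ± 2.04 CPM, and RRM2 (7.64-fold), CCNA2 (7.12-fold) and TYMS (6.77-fold) fell with 25 of 26 proliferation genes. The embryonic globin gene HBZ fell 26.6-fold, while the fetal globin gene HBG2, close in sequence to HBG1, rose 1.61-fold. LIN28A, a gene of undifferentiated cells, fell 9.95-fold and LIN28B 3.85-fold. The endothelial gene CDH5 fell 5.34-fold while KDR rose 12.8-fold to 1954 ± 25.7 CPM.

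Genes of the T lineage moved apart from each other at day 15. PTCRA, which encodes the invariant pre-T-cell receptor α chain (ENSG00000171611, chromosome 6 from 42915989 to 42925835 in GRCh38), rose from 7.48 ± 0.504 to 183 ± 7.4 CPM, 24.4-fold (adjusted p = 1.6e-40, higher in 3 of 3 libraries). The receptor recombination gene RAG1 stood at 4.17 ± 0.818 and 5.52 ± 0.24 CPM and did not pass (adjusted p = 0.098), though it passed without day 10 replicate 2, at a log2 fold change of 0.55. CD3E, part of the receptor complex on every mature T cell, had 0 counts on both days. IL7R rose 52.9-fold to 25.3 ± 1.21 CPM, GATA3 2.68-fold and TRDC, the receptor δ constant gene (ENSG00000211829, chromosome 14 from 22462932 to 22465787), 51.5-fold to 5.81 ± 0.429 CPM. The receptor γ constant gene TRGC1 (ENSG00000211689, chromosome 7 from 38257879 to 38265678) rose 7.85-fold to 13.2 ± 2.46 CPM, with its split from the similar gene TRGC2 uncertain. CD7, an early T and natural killer marker, fell 3.31-fold.

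Over the whole comparison, 8562 genes were higher at day 15 and 6214 lower, and 5698 and 2957 of these differed at least 2-fold. Of 31 gene lists with enough tested members, 16 were called by camera, 12 up and 4 down. Myeloid genes (23 of 23 higher, median log2 fold change 3.95, adjusted p = 8.1e-44), mast cell, basophil and eosinophil genes (14 of 15, 4.17, 3.6e-24), interferon response genes (17 of 18, 2.71, 6.4e-26) and megakaryocyte genes (16 of 16, 1.73, 7.2e-19) went up. The interferon genes IFIT2 (204-fold) and IFIT3 (60-fold) led theirs, and FOS (79.3-fold) led the immediate early and heat shock list, of which 17 of 20 rose (median 1.58). Migration receptors (14 of 16 higher, median 2.33), cytokine receptors (18 of 20, 1.55) and γδ fate transcription factors (13 of 16, 1.42) also went up. Proliferation (median -2.4), glycolysis (14 of 19 lower, -0.42) and the list of recombination and pre-receptor genes (9 of 12 lower, -0.83) went down, the last through end-joining and chromatin genes such as PRKDC (3.88-fold) and HMGB2 (3.15-fold) rather than RAG1 or PTCRA. For these lists the calls held with an estimated correlation, and the counts adjusted over the list alone were the same except in glycolysis, where 4 rather than 3 genes were higher. The calls of thymocyte surface markers (median 1.43, adjusted p = 0.08 with an estimated correlation), cytotoxic genes (3.48, 0.0652), type 2 innate lymphoid genes (3.03, 0.0912), activation receptors (3.58, 0.08) and the fetal LIN28B list (-0.3, 0.08) were lost there. Erythroid genes were not called and their median (0.65) and mean (-0.59) differed in sign. Endothelial genes were not called either, with a median of -0.67, a mean of -0.28 and a test direction of up.

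From day 15 to day 20, both labelled T progenitors, platelet genes fell while myeloid, antigen-presenting and matrix genes rose. TUBB1 fell 95.9-fold to 49.2 ± 2.8 CPM, GP1BB 117-fold and GP6 97.4-fold, and all 16 megakaryocyte genes fell. The transcription factor genes TAL1 (34.2-fold) and MEIS1 (25.5-fold) fell with them, as did the endothelial and platelet genes VWF (78.3-fold) and MMRN1 (88.4-fold). The interferon response gene IFIT1 fell from 2491 ± 25 to 50.5 ± 1.71 CPM, and HBG2 fell 64.6-fold. P2RY12 (243-fold), KCND3 (251-fold) and XIRP2 (292-fold) were among the largest decreases.

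In the same interval MPO, the main enzyme of neutrophil granules (chromosome 17 from 58269856 to 58280935), rose from 3532 ± 76.7 to 11860 ± 46.9 CPM. The macrophage receptor gene CSF1R rose 9.41-fold to 734 ± 11.8 CPM, CD14 9.25-fold and CTSG 6.28-fold. HLA-DRA, an MHC class II gene, rose from 5.59 ± 0.91 to 121 ± 3.98 CPM, and HLA-DQA1 rose 19.7-fold. KIT, a receptor gene of progenitors and mast cells, rose 5.79-fold, and TPSAB1, which can share reads with TPSB2, rose 15.2-fold. The collagen gene COL3A1 rose from 658 ± 10.7 to 4100 ± 55.2 CPM and the matrix gene DCN 14.2-fold. The epithelial gene CDH1 rose 376-fold to 164 ± 4.56 CPM, and TMEM151A at least 355-fold.

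PTCRA fell 111-fold to 1.65 ± 0.26 CPM, and TRDC fell 3.96-fold to 1.46 ± 0.548 CPM (adjusted p = 6e-06). TRGC1 rose 1.87-fold to 24.8 ± 1.7 CPM, TCF7 2.98-fold to 9.92 ± 1.1 CPM and the Notch target DTX1 7.61-fold to 5.08 ± 0.507 CPM, while the Notch targets HES4 (16.6-fold) and HEY2 (12.8-fold) fell. The Notch list was not called in the 4 comparisons (10 higher and 4 lower at day 15, 6 and 10 at day 20, 8 and 3 at day 25 against day 20, and 7 and 7 at day 25 against day 10). CD3E was detected at 0.325 ± 0.0411 CPM, at least 7.51-fold above day 15, from 33 counts over 3 libraries. RAG1 fell 1.76-fold, and BCL11B rose to 0.498 ± 0.183 CPM (adjusted p = 0.011), a call lost without day 15 replicate 2 (log2 fold change 1.57). The adaptor genes LAT (18-fold) and GRAP2 (80.7-fold) and the kinase gene FYN (17.2-fold) fell. Summed CD3D, CD3E and CD3G stood at 0.0403 ± 0.0699 CPM at day 15, and all 16 megakaryocyte genes fell over the same interval. These 3 falls therefore cannot be assigned to T cells.

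Here 8197 genes were higher and 7271 lower, with 4781 and 4488 at least 2-fold. Camera called 10 lists, all of which held with an estimated correlation. Megakaryocyte (median log2 fold change -5.71, adjusted p = 1.6e-70), erythroid (17 of 19 lower, -3.43, 9.9e-15), interferon response (15 of 18 lower, -1.53, 2.5e-14) and endothelial genes (17 of 24 lower, -1.58, 8.6e-07) went down. Myeloid (23 of 23 higher, 1.78, 1.1e-20), stromal (13 of 18, 1.35, 2.7e-08), MHC class II and dendritic cell (16 of 19, 2.76, 3.8e-05) and proliferation genes (22 of 26, 0.96, 0.0011) went up. CD3 and receptor signalling genes were called down (0.00029) although 8 rose and 9 fell, with a median of 0.03 and a mean of -0.58. Stem and progenitor genes were called down (0.014) with a median of 0.1, a mean of -0.21, and 10 higher against 11 lower, and this call was lost with library-size scaling. All 11 HOXA genes rose (median 2.4), HOXA10 9.27-fold, yet the list was not called (adjusted p = 0.19). Adjusted over the list alone, the counts of these lists were the same.

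From day 20 to day 25, when the labels change to mature γδ T cells, the protease genes MMP12 and MMP7 were among the largest increases, and proliferation and erythroid genes fell. MMP12 went from 19.6 ± 1.02 to 499 ± 7.33 CPM and MMP7 from 15.1 ± 2.01 to 360 ± 6.04 CPM, and TM4SF19 (34.3-fold), ADRA2B (79.5-fold) and SLC6A7 (80.6-fold) rose further in proportion. TYROBP rose 2.22-fold to 589 ± 8.37 CPM, HAVCR2 4.64-fold to 297 ± 3.65 CPM, CD52 5.17-fold and KIT 2.02-fold. EPX fell from 1719 ± 7.94 to 173 ± 7.07 CPM, PRG2 9.46-fold and PRG3 10.4-fold. MPO fell 2.74-fold to 4332 ± 42 CPM, while S100A12 rose 2.67-fold. The liver-associated genes TTR (11.4-fold) and APOC3 (10.7-fold) fell.

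T-lineage genes moved in both directions or did not pass. Of T-lineage transcription factors 4 were higher, 5 lower and 8 not called, and of thymocyte surface markers 6, 5 and 6. Neither list was called by camera. TRDC fell 3.65-fold to 0.379 ± 0.299 CPM (adjusted p = 0.00033), TRGC1 2.46-fold to 10 ± 0.872 CPM (8.8e-13) and TRGC2 2.84-fold to 4.9 ± 0.0444 CPM. CD3E stood at 0.325 ± 0.0411 and 0.168 ± 0.105 CPM and did not pass (0.34). PTCRA rose 3.72-fold to 6.11 ± 0.207 CPM and DTX1 2.61-fold to 13.3 ± 0.825 CPM. TCF7 fell 1.49-fold and NKG7 1.47-fold, and GATA3 (0.93), RAG1 (0.99) and BCL11B (0.19) did not pass. PRF1 stood at 3.21 ± 0.859 and 2.06 ± 0.293 CPM (0.054), and passed as lower without day 20 replicate 2 (log2 fold change -0.83) or without day 15 replicate 2 or 3 (-0.64 each). GZMB had 12 counts at day 20 and 4 at day 25.

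This was the smallest of the 4 comparisons, with 4952 genes higher and 5071 lower, of which 1353 and 1385 differed at least 2-fold. Camera called 10 lists, 1 up and 9 down. Megakaryocyte (15 of 16 lower, median -1.96, adjusted p = 6.3e-33), proliferation (26 of 26, -0.81, 8e-20), interferon response (17 of 18, -0.8, 2.2e-11) and erythroid genes (17 of 19, -3.76, or -3.49 with genes at 0 on a day set to their bound) went down. Mast cell, basophil and eosinophil genes were called down (median -0.61, adjusted p = 5e-15), with 6 higher and 7 lower. That list was split, as EPX fell 9.96-fold and CLC 2.77-fold while CPA3 rose 2.1-fold and TPSAB1 2.83-fold, so mast cell genes did not fall as a group. Each of these calls held with an estimated correlation, and adjusted over the list alone the counts were the same. The calls of stem and progenitor genes (median -0.66, adjusted p = 0.0589 with an estimated correlation), pluripotency genes (-0.94, 0.088), cytotoxic genes (-0.65, 0.149), the fetal LIN28B list (-0.45, 0.0589) and γδ fate transcription factors, the list that went up (0.11, 0.111), were lost there. The pluripotency call was also lost with library-size scaling (median -1.11), and the γδ fate call without day 20 replicate 2 (median 0.13), day 20 replicate 3 (0.14) or day 25 replicate 2 (0.13). Of the cytotoxic genes 1 was higher and 11 lower, and adjusted over the list alone 2 and 12. The myeloid list was not called (13 higher, 8 lower, median 0.16).

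Day 25 against day 10 spans the steps labelled from haematopoietic progenitor to mature γδ T cell, and myeloid and mast cell genes rose while red cell and platelet genes fell. CHIT1 reached 534 ± 3.63 CPM from 0 counts, at least 18000-fold, MMP12 rose at least 16800-fold and S100A12 at least 7720-fold. CD14 stood at 0.0167 ± 0.029 CPM at day 10 and 425 ± 5.19 CPM at day 25, and S100A8 rose 839-fold to 1115 ± 124 CPM. SPI1, a transcription factor gene of myeloid cells, rose 9.12-fold, CPA3 2230-fold, HLA-DRA 2140-fold and COL1A1 4.92-fold. HEMGN fell 802-fold, and HBG2, uncertain against HBG1, fell from 216 ± 19.9 to 0.232 ± 0.096 CPM. The platelet gene PF4 (chromosome 4 from 73981077 to 73982124) fell 184-fold and SELP 146-fold.

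CD34 fell 18.4-fold to 1.1 ± 0.275 CPM, CD7 8.26-fold to 2.22 ± 0.169 CPM and LIN28A 114-fold. IL7R rose 128-fold to 61.2 ± 2.97 CPM, RUNX3 66-fold, IKZF3 to 5.71 ± 0.17 CPM, DTX1 16.4-fold and CD1A 48.4-fold to 9.23 ± 0.927 CPM. NKG7 rose 24-fold to 46 ± 3.85 CPM, while GZMB fell 11-fold. TRGC1 rose 5.97-fold, and TRDC rose 3.56-fold (adjusted p = 0.008), a call that was lost without day 10 replicate 1 (log2 fold change 1.3) or without day 25 replicate 2 (0.90). ZBTB16, a transcription factor gene of innate-like T cells, fell 16-fold. PTCRA was 1.22-fold lower (0.005), and RAG1 did not pass (0.082) except as lower without day 10 replicate 1 or day 25 replicate 2 (log2 fold change -0.56 each).

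In this comparison 7781 genes were higher and 7264 lower, and 5339 and 3330 differed at least 2-fold. Camera called 22 lists, 12 up and 10 down, of which 17 held with an estimated correlation. Myeloid (23 of 23 higher, median 5.79, adjusted p = 9.9e-83), mast cell, basophil and eosinophil (15 of 15, 6.33, 1.1e-14), stromal (18 of 18, 1.9, 6.9e-12) and MHC class II and dendritic cell genes (18 of 19, 4.56, or 4.37 with bounds) went up. So did immediate early (14 of 20, 2.2), migration (15 of 16, 3.41), type 2 innate lymphoid (6 of 7, 5.23), thymocyte surface (12 of 17, 3.13) and γδ fate genes (13 of 16, 2.57, and 14 adjusted over the list alone). Megakaryocyte (16 of 16 lower, -5.7, 2.3e-52), proliferation (26 of 26, -2.26, 1.1e-26), erythroid (19 of 19, -8.03, or -7.4 with bounds) and endothelial genes (18 of 24, -2.31) went down. Stem and progenitor (12 of 24 lower and 10 higher, -0.81) and pluripotency genes (6 of 11 lower and 3 higher, -1.08) were called down. So were recombination and pre-receptor genes (10 of 12 lower and 1 higher, -0.83). CD3 and receptor signalling genes were called down too (9 of 18 lower, 5 higher, median -0.26, mean -0.06, adjusted p = 0.00015). Neither these nor stem and progenitor genes fell as a group. Apart from γδ fate genes, the counts adjusted over the list alone were the same in these lists. The calls of T-lineage transcription factors (median 1.23, adjusted p = 0.115 with an estimated correlation), cytotoxic genes (1.05, 0.184), activation receptors (2.45, 0.121), the fetal LIN28B list (-0.2, 0.0833) and cholesterol synthesis (-0.44, 0.0975) were lost there. The call of T-lineage transcription factors was also lost without day 10 replicate 1 (median 1.18), day 20 replicate 1 or day 20 replicate 3 (1.23 each), and with library-size scaling (1.15).

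**Figure D2:**
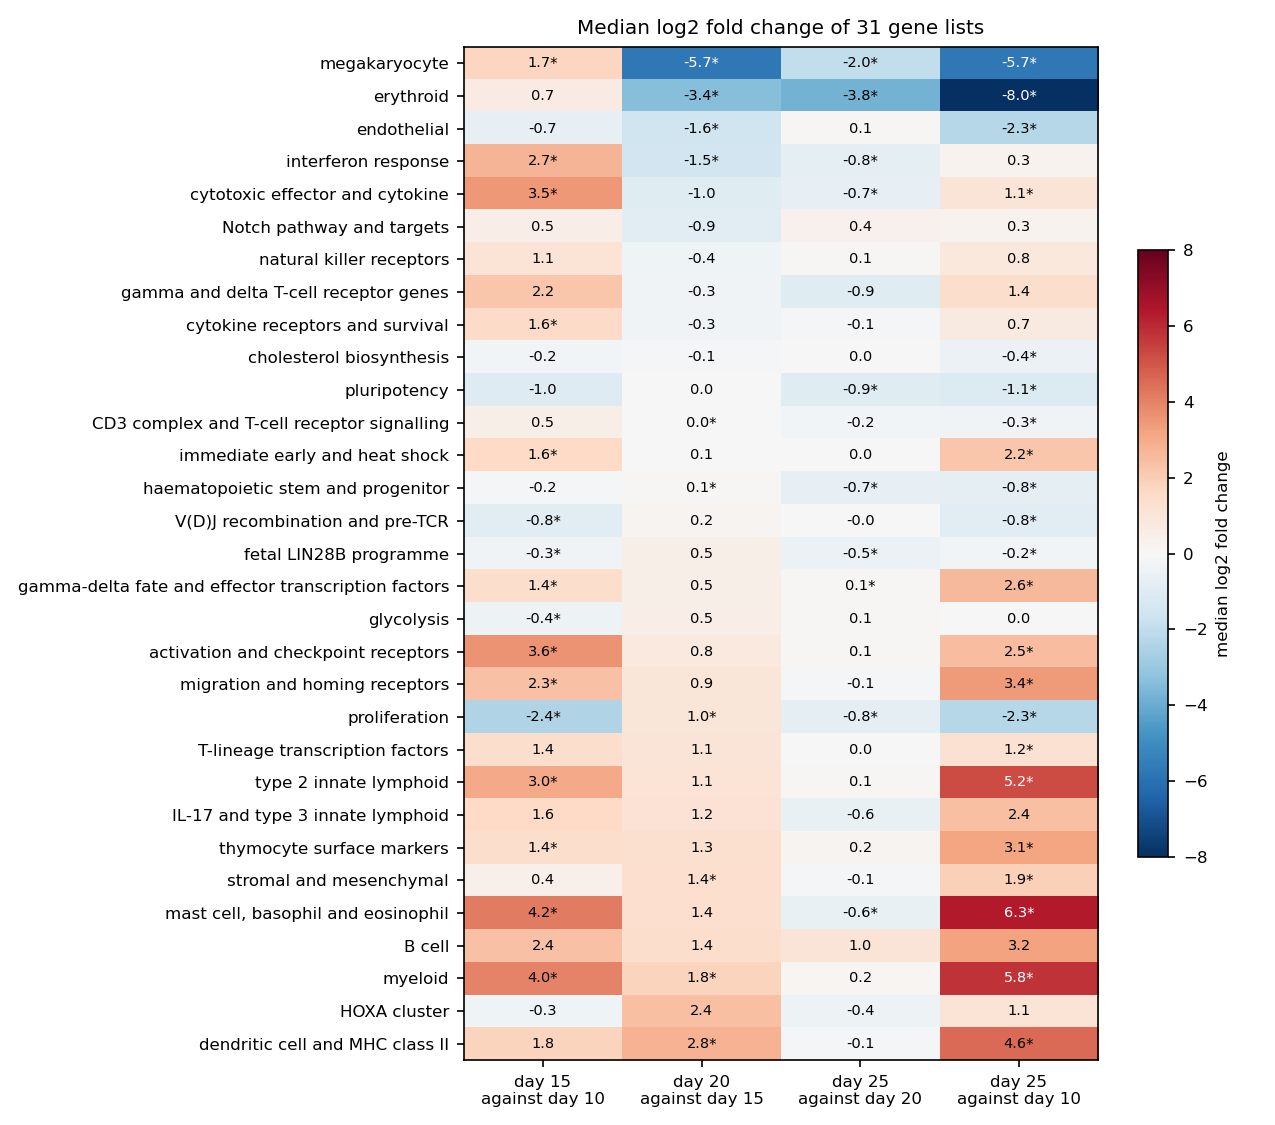
Each cell gives the median log2 fold change of a gene list (vertical axis) in a comparison of days (horizontal axis), in colour and number, with an asterisk where camera's adjusted p was under 0.05. Megakaryocyte genes went up at day 15 (1.73) and down at day 20 (-5.71), and myeloid genes went up at both.

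Several genes of mature T cells were at or near the detection limit at day 25, the day labelled mature γδ T cells. The labels do not say whether cells were sorted or the whole culture was taken. A count of 0 over the 3 day 25 libraries allows up to 0.029 CPM. CD3D and CD3G had 0 counts and CD3E 17, LCK stood at 0.125 CPM, and GZMA and GZMB had 4 counts each. The δ variable gene TRDV1 had 0 counts in all 12 libraries, and TRDV2 and TRGV9 had 5 and 20 counts at day 25. Summed over CD3D, CD3E and CD3G, the level was 0.0545 ± 0.0506 CPM at day 10, 0.0403 ± 0.0699 at day 15, 0.754 ± 0.211 at day 20 and 0.168 ± 0.105 at day 25. The γδ constant genes TRDC, TRGC1 and TRGC2 together had 254, 1855, 4063 and 1609 counts on days 10, 15, 20 and 25, against 62, 16, 29 and 37 for the αβ constant genes TRAC, TRBC1 and TRBC2, which were too low to test. The variable genes differed from this, with 411, 429, 378 and 388 counts for γδ (TRDV and TRGV) and 236, 680, 123 and 57 for αβ (TRAV and TRBV), so αβ variable counts were the higher at day 15. Floors and limits cover counting error only.

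**Figure D3:**
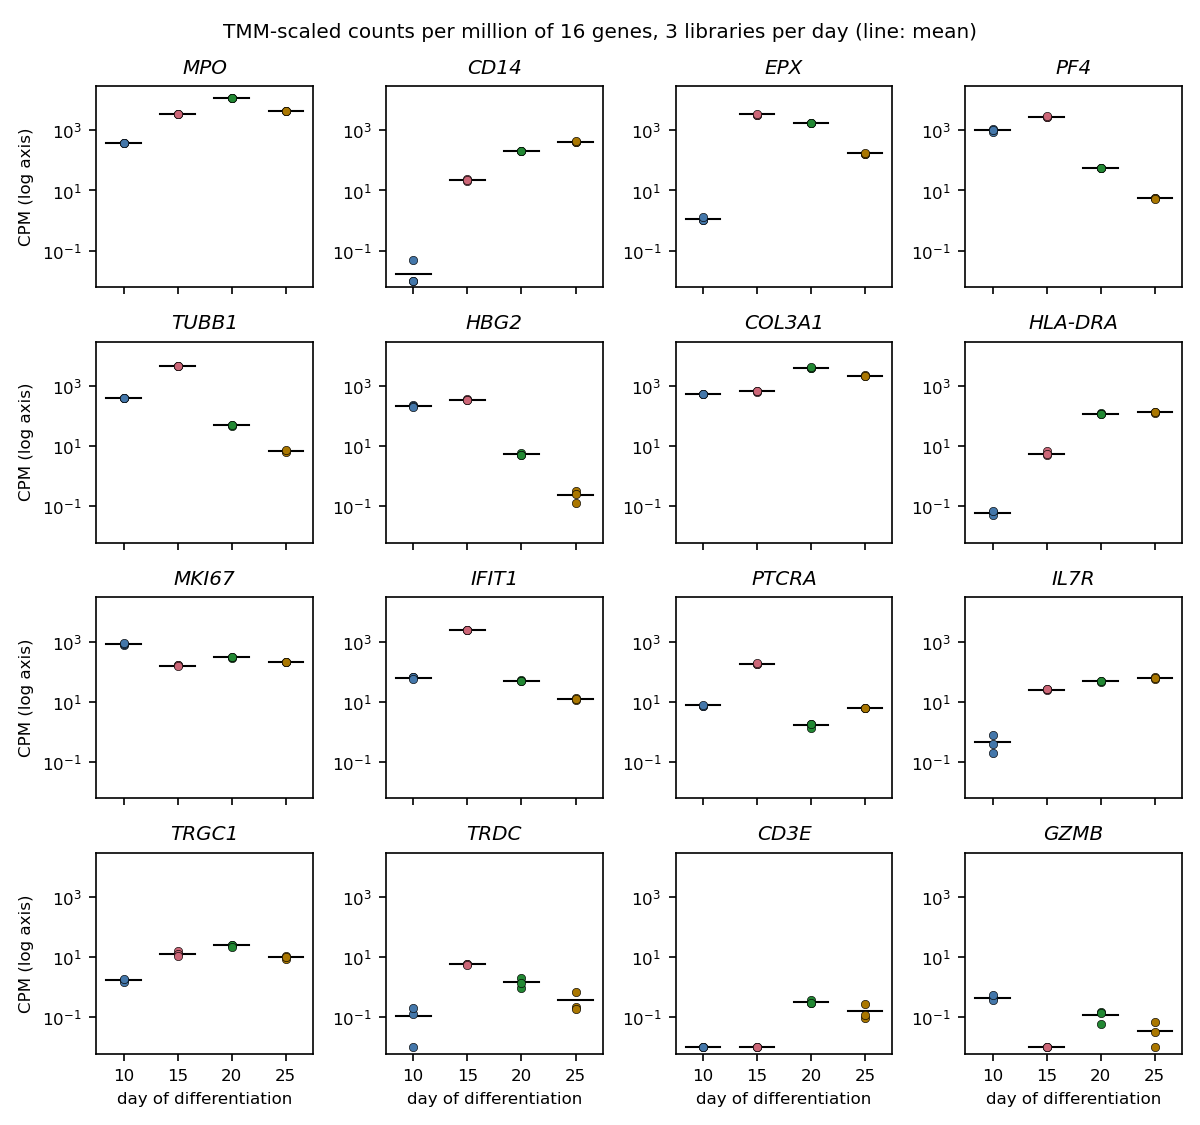
Each panel shows a gene's TMM-scaled CPM (log axis) in the 3 libraries of each day, with a line at the day's mean and values of 0 drawn at the bottom. PTCRA peaks at day 15 at 183 CPM with TUBB1 at 4721 CPM, and CD3E reaches at most 0.373 CPM in any library.

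Stage genes were those at least 2-fold above each of the other 3 days. Day 15 had 2891, day 25 had 986, day 10 had 705 and day 20 had 363. KCND3 (249 CPM), P2RY12 (143 CPM) and PDZK1IP1 (395 CPM) led day 15, each under 4 CPM on the other days. TM4SF19, MMP12 and MMP7 led day 25 with ADRA2B and SLC6A7. HBZ, SLC30A10 and KCNK17 were among the leading genes of day 10, and the liver-associated genes ALB (122 CPM), TTR and APOC3 led day 20 with SLC5A12 and AGTR1.

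The makeup of the libraries differed among days. Haemoglobin genes took 0.0619 ± 0.00219% of counts at day 10, 0.0857 ± 0.00181% at day 15, 0.00269 ± 0.000209% at day 20 and 0.000231 ± 2.79e-05% at day 25 (exact permutation p = 6.5e-05, the smallest that the 15400 partitions can give). Ribosomal protein genes took 3.98 ± 0.0772%, 1.25 ± 0.0163%, 3.67 ± 0.0819% and 2.18 ± 0.0205% (exact permutation p = 6.5e-05). Mitochondrially encoded genes took 5.45 ± 0.263%, 3.54 ± 0.0767%, 5.47 ± 0.292% and 5.4 ± 0.243% (exact permutation p = 0.018), and the 10 most counted genes 7.65 ± 0.162%, 7.86 ± 0.0358%, 7.94 ± 0.192% and 8.74 ± 0.0883% (exact permutation p = 0.00091). The γδ share of receptor constant counts was 80.4 ± 6.15%, 99.2 ± 0.309%, 99.3 ± 0.0794% and 97.6 ± 0.83% (exact permutation p = 0.00045), a share that leaves out the variable genes. At day 25 the γδ constant level came mostly from γ genes, with TRGC1 at 10 and TRGC2 at 4.9 CPM against 0.379 CPM for TRDC. The αβ constant genes held at most 62 counts on any day. A high γδ share therefore does not show that γδ T cells were present. The permutation tests of shares were over all 4 days with the F statistic, which has no direction, and were not adjusted for their number.

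Scaling moved the balance of directions. TMM set the median log2 fold change over all genes at 0.20 for day 15 against day 10 and 0.10 for day 20 against day 15, where library-size scaling alone gave -0.32 and 0.73. Under library-size scaling 39.2% of the genes called at day 15 were higher rather than 57.9%, 72.1% rather than 53% at day 20 and 31.4% rather than 49.4% at day 25 against day 20. Day 25 against day 10 gave 48.7% rather than 51.7%. NOTCH1 and ZBTB16, which rose at day 15 by less than this shift (log2 fold changes 0.09 and 0.12), took the opposite sign with library-size scaling (-0.44 and -0.41). The NOTCH1 call was also lost on leaving out any 1 of several libraries, such as day 10 replicate 2 or day 15 replicate 3. The ZBTB16 call was lost without day 15 replicate 2.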

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

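None of these alternatives was chosen after the results were seen. The numbers of called genes stayed within 1.5 times those reported under DESeq2 size factors, DESeq2, limma-voom, both other filters, thinned libraries, the smaller gene set, fits to the compared days alone where these could be made, and an adjusted p under 0.01. A minimum change of 2-fold left 5698 genes higher and 2957 lower at day 15, 4781 and 4488 at day 20, 1353 and 1385 at day 25 against day 20, and 3330 lower at day 25 against day 10, and a stage threshold of 4-fold left 95, 1368, 99 and 293 genes at days 10, 15, 20 and 25, as fewer genes can pass. With library-size scaling, 4530 genes were lower at day 20 than day 15, and stage genes numbered 1852 at day 15 and 561 at day 20. An estimated correlation left 5 called lists for day 25 against day 20. Signs reversed with library-size scaling for NOTCH1 (-0.444) and ZBTB16 (-0.411) and TYROBP (-0.009) at day 15 against day 10, RUNX1 (0.363) at day 20 against day 15, and NOTCH1 (-0.153) and the γδ fate transcription factor list (-0.056) at day 25 against day 20. NOTCH1 and ZBTB16 at day 15 also reversed without a filter (-0.115 and -0.081) and with only the libraries of the compared days (-0.091 and -0.058), and the cause was not tested. Leaving out each library in turn gave 8305 to 8659 genes higher and 6009 to 6283 lower at day 15, 7952 to 8302 and 7085 to 7382 at day 20, 4583 to 5065 and 4547 to 5088 at day 25 against day 20, 7630 to 7986 and 6912 to 7300 at day 25 against day 10, and 18334 to 18509 among the 4 days. Stage genes ranged from 672 to 709, 2793 to 2929, 340 to 373 and 934 to 1012 at days 10, 15, 20 and 25, and called lists from 16 to 17, 10 to 11, 9 to 10 and 21 to 22 in the order of the comparisons. Of 526 values of named genes, 506 of them called, 69 lost their call under at least 1 alternative, 7 gained one, and 17 lost it on leaving out 1 library. The shares of counts kept their call under the alternatives run. Genes near the floor, such as CD3E and GZMB, are limited by depth.

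With the replicate number as a replicate block, 8439 genes were higher and 6153 lower at day 15, 8109 and 7192 at day 20, 4832 and 4928 at day 25 against day 20 and 7705 and 7168 at day 25 against day 10, 18102 differed among days, and 16, 10, 10 and 22 lists were called. Stage genes numbered 688, 2854, 359 and 960. The labels do not say that a number links libraries of different days: deviations of libraries with the same number correlated between -0.016 and 0.016, those with other numbers between -0.027 and 0.025, and 4 of 12 libraries lay closest to their own number.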

Other observations

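The tests of the CD3, PTCRA and replicate-spread patterns, the counts of genes under other splits and the lists named next were chosen only after the results were seen. These lists hold genes whose rise had been seen before the lists were made (CHIT1, OLFM4, CEACAM8, DEFA1, DEFA3, ALB, TTR, APOC3 and CDH1), so their counts partly restate those rises. Tissue macrophage genes, of which CD163 is also a myeloid list gene, rose at both later steps: 17 of 17 at day 20 against day 15 and 17 of 17 at day 25 against day 20. APOE reached 2840 ± 32.9 CPM, CHI3L1 8650 ± 151 CPM and GPNMB 1780 ± 37.9 CPM at day 25, from 65.4 ± 3.19, 0.888 ± 0.523 and 0.11 ± 0.102 at day 10. Osteoclast genes rose in 10 of 11 tested members from day 20 to day 25, with MMP9 going from 68 ± 2.66 to 1160 ± 31.9 CPM and ACP5 from 201 ± 7.03 to 855 ± 11.7 CPM. Neutrophil granule genes rose in 14 of 14 members at day 15, with LTF at 49.4 ± 2.94 CPM there and 397 ± 5.36 CPM at day 25. Liver and yolk sac endoderm genes rose in 15 of 16 members at day 20 and fell in 13 of 16 at day 25, AFP going from 53.5 ± 2.18 to 419 ± 3.6 and then 83.3 ± 0.939 CPM. Epithelial genes rose in 11 of 12 at day 20 and fell in 7 of 12 at day 25, with KRT8 at 663 ± 19.7 and 244 ± 7.93 CPM.

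CD3 genes and TRDC (0.379 CPM) were low at day 25, while TRGC1 stood at 10 CPM. An exchange of libraries between days is argued against, since the highest summed level of CD3D, CD3E and CD3G in any of the 12 libraries was 0.912 CPM, while an exchange with material from outside the series stays open. Loss of receptor reads in counting is argued against as the whole cause, because 12 T-cell genes outside the receptor loci had a median of 0.78 CPM at day 25. Whether a few T cells were present among many other cells cannot be told apart from other sources of 0.168 CPM of summed CD3 genes, since no library of pure T cells was in the series.

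PTCRA was high at day 15. Pre-T cells as its main source are argued against, since CD3D, CD3E and CD3G, abundant in such cells, summed to at most 0.121 CPM in a day 15 library against 183 CPM of PTCRA. PTCRA rose and fell as 16 of 16 megakaryocyte genes did. As 17 of 18 interferon response genes also rose at day 15 and 15 of 18 fell at day 20, a shared time course does not name a source. PTCRA rose again from 1.65 to 6.11 CPM at day 25 while 15 of 16 megakaryocyte genes fell. That level is small beside 183 CPM and does not bear on the day 15 peak, whose source stays open.

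Replicate libraries differed little. Over the 12 pairs within days, genes of high count had an implied coefficient of variation of at most 3.26%, which argues against separate cultures that vary by 10% or more per gene. The spread was 3.49 to 5.16 times that of Poisson counting of independent reads, which does not exclude repeat libraries of the same RNA. In 12 of 12 libraries genes with a count of 2 outnumbered those with 1 (1405 to 1602 against 792 to 1006), which would follow if fragments were counted as 2 reads, though the labels give single reads. Whether the replicates were separate cultures with little variation, divisions of the same culture or repeat libraries of the same RNA stays open.

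Other splits of the libraries were counted for each comparison. With 3 libraries against 3 the 10 splits are too few for a share under 0.05: the real split, 1 of them, called 14776, 15468, 10023 and 15045 genes in the order of the comparisons and the highest of the others called 0, and for lists the real values were 16, 10, 10 and 22 and the highest others 13, 8, 6 and 16. Over 50 splits into 4 groups, as many genes differed among groups as among days (18256) in 1 split, the real one (highest other 6766). Each day's number of stage genes was set against the largest number in any group of a split. The stage genes of day 15 (2891) were matched in 1 split and those of day 25 (986) in 2, both shares under 0.05. Those of day 10 (705) and day 20 (363) were each matched in 3 splits, the real one included, which is not under 0.05. The other matches came from splits that kept a real day whole, so these shares do not rank the days. The highest other number of stage genes was 2313. Values above 0 came only from the 5 other splits that kept a whole day together as a group, and splits without a whole day gave at most 0. Every other split mixed libraries of different days, which widens the spread within groups and lowers gene calls. The lead of the real split was therefore built in, so no conclusion is drawn from it. The shares also depended on which splits were drawn. Since the replicates may be repeat libraries of the same RNA, splits of libraries cannot exclude chance differences between cultures.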
